A study of Homo sapiens with 23 samples.

How the data were processed

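The libraries were made from a reporter line of H9, an established human embryonic stem cell line, in which the promoter of CRX drives green fluorescent protein (GFP). Cells had been grown into 3D neural retina, dissociated and sorted by GFP at 4 ages, and undifferentiated cells of the line were sequenced beside them. Poly(A) RNA was read as single-end reads of 76 bases by stranded RNA-seq. The deposited tables held estimated counts per transcript for 95311 transcripts, with no scaling to a common total. The submitters' processing notes named Bowtie2, TopHat2, eXpress, edgeR and limma and the build GRCh37.p13, and gave neither versions nor the role of each tool. eXpress assigns reads that map to several transcripts by likelihood, which makes its estimated counts fractional. Only the estimated counts were deposited, so an analysis of eXpress effective counts was not run.

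Counts of the transcripts of each Ensembl gene were summed, giving 20721 genes, of which 20327 were protein coding by the gene type in the tables. All measured columns of the 23 libraries were read. Totals ran from 40.6 M to 52.6 M estimated counts per library (M, 1e6), with a median of 46.1 M. Counting error alone is therefore small for a gene at 1 CPM (counts per 1e6 counts), and the limits given for genes at 0 cover counting error only. Gene symbols that a spreadsheet had turned into dates, 26 in number, were restored from the Ensembl identifiers. Positions are those of the deposited tables on GRCh37.

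The column of the third undifferentiated library was out of step with its transcripts. It lacked 2 values, and compared with the second library its values moved out of place after the first 32756 transcripts and again after 84329, so that 65.6% of the transcripts carried the value of another transcript. Both estimated breaks lay close to a transcript of NR2E3, the only gene with transcripts close to both, and were placed there. With the 2 missing values put there, the correlation across transcripts with the second library (log2 of count plus 1; transcripts are not independent replicates) went from 0.483 to 1.00, against 0.896 between the first and second libraries. The third column, realigned, matched the second far more closely than any other 2 replicates matched, with a mean squared difference per gene, in units of counting variance, of 0.014 against 41.4 or more for all other pairs of sorted or undifferentiated replicates. The second and the third column were therefore averaged and counted as 1 library, which left n = 2 undifferentiated libraries and 22 libraries in all.

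Genes were tested with the quasi-likelihood test of edgeR 4.0.16 (TMM scaling, filterByExpr, robust estimation) on gene counts rounded to whole numbers. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. One fit held the 20 sorted libraries in 8 groups of day and fraction (17150 genes tested, common biological coefficient of variation 33.4%). A second fit held the undifferentiated libraries and both fractions of day 37, 7 libraries in all (16737 genes, 28.7%). The 12 comparisons were GFP-positive against GFP-negative cells averaged over the 4 days and at each day, GFP-positive cells between successive days and from day 37 to day 90, GFP-negative cells from day 37 to day 90, the difference between these last changes (an interaction contrast), and GFP-positive cells of day 37 against undifferentiated cells. The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these samples. Levels are CPM from library totals scaled by TMM; log2 fold changes are those of edgeR with their standard error (SE).

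For the 24 gene lists (476 genes, 464 tested), camera of limma 3.58.1 compared the genes of a list with all others, with its preset correlation of 0.01 and again with a correlation estimated from the data; fry was run as another test. List p-values are two-sided and adjusted over the 24 lists of a comparison. Counts of called members are given over all genes tested and adjusted over the list alone. Camera called 187 list tests over the 12 comparisons with the preset correlation and 46 with an estimated one, and the text gives the adjusted p of both where they part. The comparisons, the tests, the lists and the rule for naming genes were fixed before the data were examined.

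The rule for naming genes had 3 parts. CRX was named in every comparison. The 5 highest and 5 lowest log2 fold changes were named among called genes with a symbol, at least 5 CPM in the higher group and no overlap between the libraries of both groups. The condition on overlap was not applied to the interaction. For a described list, up to 4 called members with the largest change and at least 1 CPM were named, with uncalled members where a list did not move. OTX2, NRL, NR2E3, ARR3, OPN1SW, RXRG, THRB, RCVRN, PAX6 and MKI67 were among the genes that could be named over time. Where a group had no counts of a gene, the fold is a lower bound against a floor of 3 counts over the group.

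The replicate numbers were checked for pairing by correlating, across genes, the deviations of same-numbered libraries from their group means. The GFP-positive libraries of days 47 and 67 (r from 0.136 to 0.436) and of days 67 and 90 (r from 0.104 to 0.422) passed the limit of 0.1 in all 3 pairs, and those of days 37 and 47 (0.0773 to 0.413) and of days 37 and 90 (0.0223 to 0.253) did not. Between fractions of a day there are only 2 pairs. Their r ran from -0.0817 to 0.137 at day 37, from 0.106 to 0.167 at day 47, from 0.138 to 0.265 at day 67 and from 0.438 to 0.539 at day 90. GFP-negative libraries of days 37 and 90 gave r of -0.288. Genes are not independent replicates, so these r carry no p. A fit with a replicate block was run for every comparison. Between fractions each combination of day and number was a block, so GFP-positive replicate 3, without a partner, did not inform the difference. In the other comparisons the replicate number was the block.

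The test was checked on simulated data with 200 changed genes. At a change of 3-fold, edgeR recovered 78.6% of them for the mean of 4 days, 48.5% at day 37, 55.1% for GFP-positive cells between days 37 and 90, 34.7% for GFP-negative cells, 21.4% for the interaction and 52.5% against undifferentiated cells. At 1.5-fold it recovered 48% for the mean of 4 days and 5.15% or less in the other 5 designs. Between 4% and 12% of its calls were false, against 22.3% to 43.4% for DESeq2. Only 200 genes were changed, while edgeR called up to 10299 in the data, and the adjusted p depends on the share changed. These percentages therefore describe the simulation and do not carry over to the calls below.

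Alternatives were DESeq2 size factors, the Wald test of DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM, an added minimum change of 2-fold, only the libraries of the groups compared, the replicate block, and each library left out in turn. Other treatments of the third undifferentiated column and a crossed block for the GFP-negative libraries of day 90 were added after the data were seen. Scripts ran in R 4.3.3 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Read alignment was not repeated, non-coding genes outside the tables were not measured, and the genes CD24, ESRG, NEFL and SPON1 of the lists were not analysed here.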

Results

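RNA was sequenced from human embryonic stem cells that carry GFP under the promoter of CRX, a transcription factor of photoreceptor precursors, and from the retinal tissue grown from them. The sorted cells formed 8 groups, GFP-positive cells (n = 3 libraries a day) and GFP-negative cells (n = 2 a day) at days 37, 47, 67 and 90 of differentiation. Undifferentiated cells of the line formed a ninth group, with 3 columns that held 2 distinct libraries (n = 2). The libraries held between 40.6 M and 52.6 M estimated counts (M, 1e6), with 13095 to 14713 genes at 1 CPM (counts per 1e6 counts) or more. Mitochondrially encoded genes took 1.60% to 5.73% of the counts and the 10 most abundant genes 4.62% to 6.67%. Levels below are mean CPM ± SD over the libraries of a group, with n as given here, and log2 fold changes are given ± SE. Genes said to change the most are taken from called genes with at least 5 CPM in the higher group and no overlap between libraries. For the interaction, overlap was not checked. In a principal component analysis of the sorted libraries the first component held 42.7% of the variance, the second 13.8% and the third 12.5%. GFP-negative replicate 2 of day 90 stood apart from the other sorted libraries on the second component.

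**Figure D1:**
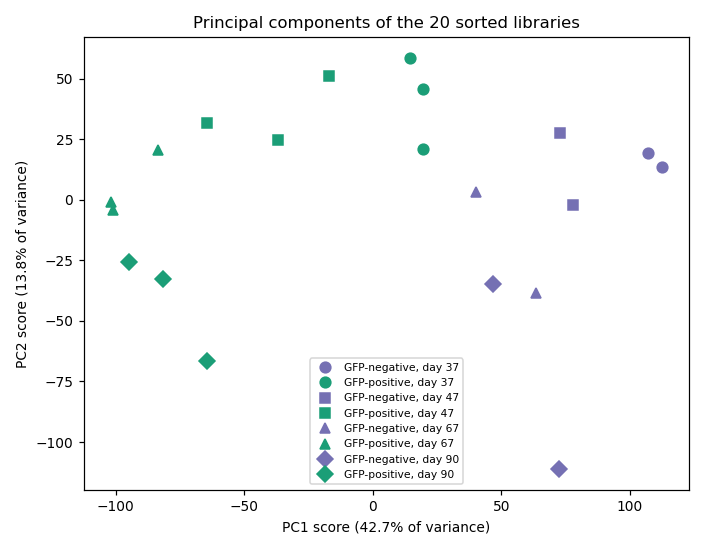
Principal components of the 20 sorted libraries (log2 CPM), with the first component (42.7% of the variance) on the x axis and the second (13.8%) on the y axis; each point is a library, coloured by fraction and marked by day. GFP-negative replicate 2 of day 90 lies far from the rest on the second component.

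The comparison of GFP-positive cells of day 37 with undifferentiated cells asked what the earliest sorted cells had gained and lost. CRX (ENSG00000105392, chromosome 19, 48322703 to 48346587) rose from 3.84 ± 0.741 to 404 ± 101 CPM (log2 6.76 ± 0.31, adjusted p = 3.88e-06). Genes of photoreceptors and of retinal neurons appeared and the genes of the pluripotent state fell. The phototransduction regulator PDC, the calcium sensor RCVRN and the cone nuclear receptor RXRG had no counts in undifferentiated cells. They reached 183 ± 92.8, 120 ± 26.8 and 95.9 ± 25.4 CPM in sorted cells, at least 5640-fold, 3700-fold and 2950-fold higher. TTR, which carries thyroid hormone and retinol-binding protein, was at least 3910-fold higher and the steroid dehydrogenase HSD17B2 at least 2650-fold higher, each from no counts. In the other direction IDO1, a tryptophan-degrading enzyme, was at least 3940-fold lower and HES3 at least 687-fold lower. VRTN went from 292 ± 30.7 to 0.0164 ± 0.0143 CPM. PRDM14, a regulator of naive pluripotency, fell by 11.25 ± 0.57 on the log2 scale and TDGF1, a NODAL co-receptor, fell by 11.08 ± 0.85.

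Of 21 pluripotency genes tested 20 were lower and 0 higher, over all genes and adjusted over the list alone (median log2 -5.77, camera adjusted p = 4.54e-25). LIN28A, an RNA-binding protein of stem cells, went from 2666 ± 122 to 4.77 ± 2.83 CPM. Among 23 pan-photoreceptor genes 20 rose, over all genes and adjusted over the list alone, with a median log2 of 7.55, or 6.68 with genes at 0 held at their bound (camera adjusted p = 4.78e-16). Of 16 photoreceptor transcription factors 14 rose and 1 fell, 15 and 1 adjusted over the list alone (median 5.68, camera adjusted p = 6.29e-17). TBX2, which patterns the retina, was at least 2170-fold higher, and NEUROD1, which drives photoreceptor differentiation, went from 0.0323 ± 0.0012 to 437 ± 119 CPM. NEUROD4 rose by 12.72 ± 0.57. OTX2, which acts upstream of CRX, was already at 153 ± 10.1 CPM in undifferentiated cells and reached 587 ± 132 (log2 1.98 ± 0.20, adjusted p = 7.55e-05). Of 15 cone genes 13 rose and 1 fell, 14 and 1 adjusted over the list alone (median 7.55, camera adjusted p = 2.04e-10; adjusted p = 0.0738 with an estimated correlation). The cone phosphodiesterase subunit PDE6H was at least 1730-fold higher and the potassium channel subunit KCNV2 at least 641-fold higher.

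Genes of other cell types rose too, inside and outside the retina. Whether such cells were among the sorted cells was not tested. Of 19 neurogenic precursor genes 18 rose, and all 19 adjusted over the list alone (median 5.68, camera adjusted p = 1.4e-15). Of 17 ganglion cell genes 14 rose and 2 fell by both adjustments (median 5.37, camera adjusted p = 1.51e-08). POU4F2, a ganglion cell regulator, stood at 74.5 ± 5.94 CPM against 0.0346 ± 0.00062, NRN1 at 69.0 ± 17.5 against 0.0339 ± 0.048 and the retinal homeobox gene LHX9 at 53.2 ± 11.3 against 0.0164 ± 0.0233. Of 22 amacrine and horizontal cell genes 17 rose and 1 fell by both adjustments (median 5.82, or 5.54 with genes at their bound, camera adjusted p = 4.79e-08; adjusted p = 0.0508 with an estimated correlation), and TFAP2B of that list was at least 158-fold higher. Among 22 retinal progenitor genes 14 rose and 3 fell by both adjustments (median 2.16, camera adjusted p = 3.49e-06; adjusted p = 0.192 with an estimated correlation). NR2E1, which keeps progenitors dividing, was at least 540-fold higher. The Notch target HES5, SIX6 and RAX, homeobox genes of the eye field, rose by 9.12 ± 0.93, 9.03 ± 0.44 and 8.22 ± 0.48. Pigment cell genes rose as well, 15 of 20 retinal pigment epithelium genes with 2 lower by both adjustments (median 3.51, camera adjusted p = 0.00323; adjusted p = 0.208 with an estimated correlation). DCT, a melanin enzyme, rose from 0.0854 ± 0.0065 to 1332 ± 322 CPM and tyrosinase (TYR) was at least 879-fold higher. Lists of non-retinal tissue rose with them. Of 18 lens, mesenchyme and neural crest genes 12 rose and 3 fell by both adjustments (median 3.06, camera adjusted p = 0.00151; adjusted p = 0.192 with an estimated correlation). The fibrillar collagen COL3A1 went from 0.0413 ± 0.018 to 1171 ± 358 CPM, above CRX, and FOXC1 was at least 442-fold higher. Of 14 forebrain genes 8 rose by both adjustments (median 3.51, or 3.09 with genes at their bound, camera adjusted p = 0.0139; adjusted p = 0.185 with an estimated correlation). Hypoxia response genes rose in 14 of 18 cases and fell in 1 by both adjustments (median 3.17, camera adjusted p = 7.39e-07; adjusted p = 0.192 with an estimated correlation). All 29 called of 33 cell cycle genes fell, again 29 adjusted over the list alone (median -2.40, camera adjusted p = 6.51e-10; adjusted p = 0.283 with an estimated correlation). The replication licensing factor CDC6 fell by 4.72 ± 0.54 and MKI67 by 1.90 ± 0.46. Genes induced by tissue dissociation, a possible mark of sorting, rose in 17 of 22 cases with 1 lower, 17 and 2 adjusted over the list alone (median 2.95, camera adjusted p = 1.71e-09; adjusted p = 0.0863 with an estimated correlation). The immediate early genes FOSB and EGR1 rose by 9.74 ± 0.75 and 7.93 ± 0.35. The log2 of FOSB was 8.85 without undifferentiated replicate 1 and 13.12 without replicate 2, and that of HES5 8.46 and 10.55, as both genes were near 0 in undifferentiated cells. With 1 library left out the log2 of NRN1 ran from 10.27 to 14.61, that of LHX9 from 10.83 to 14.24 and that of TDGF1 from -12.41 to -10.52. In all, edgeR called 10299 of 16737 genes, 5717 higher and 4582 lower, where the median log2 of all genes was 0.21.

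The comparison of both fractions asked which genes marked the cells with an active CRX promoter. Averaged over the 4 days, genes of photoreceptors and their synapse were higher in GFP-positive cells. All 33 cell cycle genes, 16 of 22 retinal progenitor genes and 16 of 19 Müller glia genes were lower in them, though these 3 lists did not pass camera with an estimated correlation (adjusted p = 0.144, 0.148 and 0.114). CRX itself was higher by a log2 of 3.50 ± 0.14 (adjusted p = 9.22e-11). The LIM-homeobox gene LHX3 (ENSG00000107187, chromosome 9, 139088096 to 139096955; 5.43 ± 0.37, adjusted p = 7.49e-09), the somatostatin receptor SSTR5 (5.36 ± 0.49), SPINK4 (4.99 ± 0.38), the photoreceptor homeobox gene RAX2 (4.98 ± 0.33) and KCNV2 (4.98 ± 0.31) showed the highest changes. SPINK4 had no counts in GFP-negative cells of day 37, so that its value depends on the prior count. At the other end stood HOX genes, which mark posterior body positions: HOXA3 (-3.51 ± 0.36, adjusted p = 7.4e-07), HOXA9 (-3.48 ± 0.68), HOXA5 (-3.44 ± 0.35) and HOXC6 (-3.32 ± 0.54), with the WNT agonist RSPO3 (-3.36 ± 0.53).

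Of 23 pan-photoreceptor genes 20 were higher and 1 lower, 21 and 1 adjusted over the list alone (median log2 3.83, camera adjusted p = 3.6e-32). RBP3, which carries retinoids between photoreceptors and pigment epithelium, was higher by 4.80 ± 0.28 and RCVRN by 4.71 ± 0.23. Cone genes followed with 15 of 17 higher and 1 lower by both adjustments (median 3.60, camera adjusted p = 2.18e-21), led by PDE6H (4.73 ± 0.25), its partner PDE6C (4.54 ± 0.24) and the cone transducin GNAT2 (4.29 ± 0.19). Of 24 photoreceptor synapse genes 21 were higher and none lower by both adjustments (median 1.69, camera adjusted p = 3.16e-25), among them the calcium-binding CABP4 (3.98 ± 0.54). All 16 photoreceptor transcription factors were called, 12 higher and 4 lower by both adjustments (median 2.36, camera adjusted p = 1.45e-14). ISL2 (4.96 ± 0.25), RXRG (ENSG00000143171, chromosome 1, 165370159 to 165414433; 3.05 ± 0.19) and the cone thyroid hormone receptor THRB (2.90 ± 0.13) were higher, as was OTX2 (2.78 ± 0.10). Of 16 rod genes 11 were higher and 2 lower by both adjustments (median 2.17, camera adjusted p = 0.00108; adjusted p = 0.148 with an estimated correlation), with the retinol dehydrogenase RDH8 at 4.63 ± 0.69 and the transcriptional repressor SAMD7 at 3.40 ± 0.86. Of 15 bipolar cell genes 6 were higher and 4 lower, 7 and 4 adjusted over the list alone (median 0.275, camera adjusted p = 0.0026), including the glutamate receptor GRM6 (4.24 ± 0.36) and CABP5 (4.11 ± 0.18) among the higher genes and SCGN (-2.93 ± 0.80) among the lower ones. Glycolysis genes were higher in 12 of 21 cases and lower in 1, 13 and 1 adjusted over the list alone (median 0.673, camera adjusted p = 0.000766; adjusted p = 0.501 with an estimated correlation), for example the neuronal enolase ENO2 (1.46 ± 0.09), ALDOA (1.43 ± 0.21) and the lactate transporter SLC16A3 (1.43 ± 0.30).

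All 33 cell cycle genes were lower in GFP-positive cells by both adjustments (median -1.92, camera adjusted p = 4.93e-22; adjusted p = 0.144 with an estimated correlation), such as the proliferation marker MKI67 (ENSG00000148773, chromosome 10, 129894923 to 129924649; -2.68 ± 0.22), RRM2 (-2.52 ± 0.27) and TOP2A (-2.42 ± 0.22). Of 22 progenitor genes 16 were lower and 2 higher by both adjustments (median -1.36, camera adjusted p = 1.63e-07; adjusted p = 0.148 with an estimated correlation). Examples were NR2E1 (-2.25 ± 0.28), the Notch effector HES1 (-2.21 ± 0.17), FGF19 (-2.20 ± 0.27) and cyclin D1, CCND1 (-2.13 ± 0.17). Of 19 Müller glia genes 16 were lower and 1 higher by both adjustments (median -1.50, camera adjusted p = 4e-06; adjusted p = 0.114 with an estimated correlation), with caveolin CAV1 at -2.61 ± 0.28, the glutamate transporter SLC1A3 at -2.27 ± 0.21 and S100B at -2.19 ± 0.50. Amacrine and horizontal cell genes were lower in 13 of 22 cases and higher in 6 by both adjustments (median -1.07, camera adjusted p = 0.012; adjusted p = 0.198 with an estimated correlation), among them TFAP2B (-2.43 ± 0.21) and the GABA-making enzyme GAD2 (-2.37 ± 0.27). Of 17 retinoic acid response genes 13 were lower and 2 higher by both adjustments (median -1.60, camera adjusted p = 0.0203; adjusted p = 0.359 with an estimated correlation), including RARRES1 (-3.20 ± 0.50) and ALDH1A2 (-2.82 ± 0.44), which makes retinoic acid.

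The remaining lists did not pass the camera test in the mean of 4 days. Ganglion cell genes were lower in 11 of 17 cases and higher in 1, 11 and 2 adjusted over the list alone (median -0.948, camera adjusted p = 0.0655), with POU4F1 at -1.81 ± 0.25. Genes of lens, mesenchyme and neural crest were lower in 10 of 17 cases and higher in 1 (median -1.64, camera adjusted p = 0.07), for example the matrix proteoglycan DCN (-2.85 ± 0.62) and FOXC1 (-2.79 ± 0.30). Forebrain genes were lower in 7 of 14 cases (median -1.12, camera adjusted p = 0.0992), with NEUROD6 at -2.60 ± 0.88. Pigment epithelium genes went both ways, 4 higher and 5 lower of 20 (median 0.182, camera adjusted p = 0.537). Counts over all genes and adjusted over the list alone were equal for these 3 lists. Neurogenic precursor genes split into 8 higher and 10 lower of 19, with a median of -0.402 below 0 and a mean of 0.101 above it (camera adjusted p = 0.887), and cell surface marker genes into 6 higher and 11 lower of 25 (median -0.329, mean 0.124, camera adjusted p = 0.817). Ciliary genes (median 0.0531, camera adjusted p = 0.127), Notch pathway genes (-0.18, 0.669), hypoxia genes (-0.103, 0.928), pluripotency genes (-0.253, 0.156), dissociation stress genes (-0.344, 0.0703) and mitochondrially encoded genes (0.43, 0.0526) did not pass either. The calls of SCGN and NEUROD6 each rested on single GFP-negative libraries. Without replicate 2 of day 90 SCGN was at -1.29 (adjusted p = 0.189) and NEUROD6 at -2.25 (adjusted p = 0.0509). SCGN was also lost without replicate 2 of day 67 (-1.93, adjusted p = 0.0708) and NEUROD6 without replicate 1 of day 47 (-0.26, adjusted p = 0.893). In all, edgeR called 9704 of 17150 genes, 4652 higher and 5052 lower in GFP-positive cells.

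**Figure D2:**
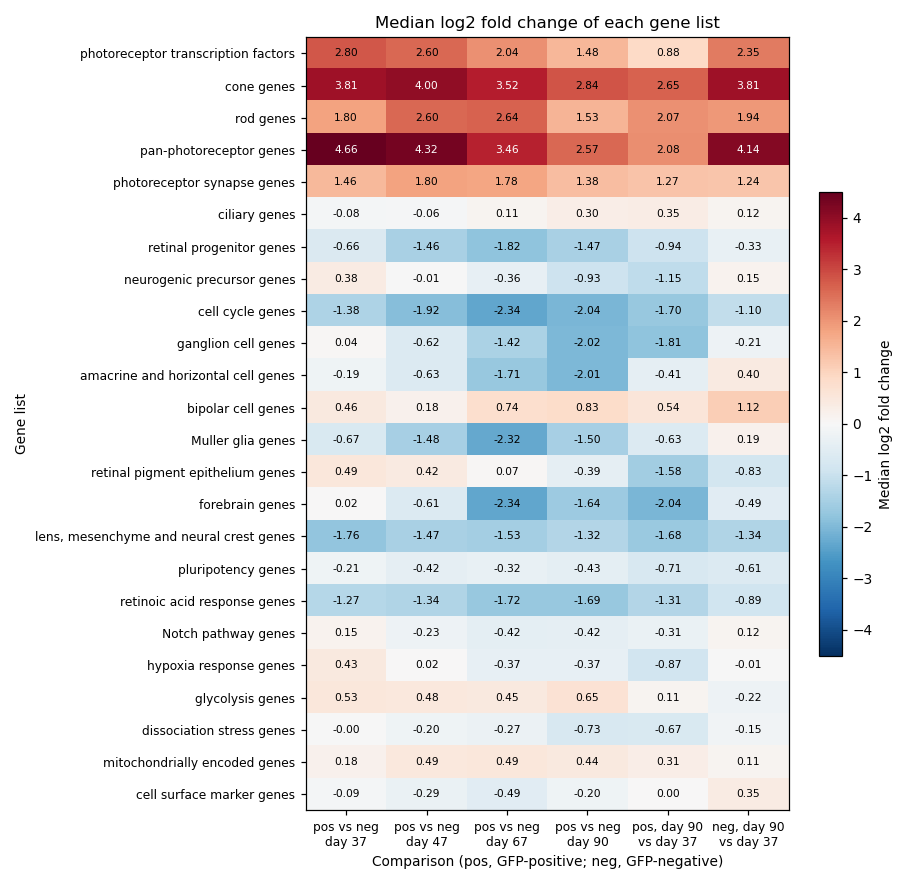
Median log2 fold change (colour and printed value) of the 24 gene lists, 1 list per line, for GFP-positive against GFP-negative cells at each of the 4 days and for day 90 against day 37 in each fraction. The photoreceptor lists lie above 0 at every day and the cell cycle list below 0.

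At day 37 the fractions already differed in cone and photoreceptor genes. CRX was at 404 ± 101 CPM in GFP-positive and 19.2 ± 0.898 in GFP-negative cells (log2 4.34 ± 0.30, adjusted p = 2.38e-07). Large differences were those of KCNV2 (6.92 ± 0.74), PDE6C (6.83 ± 0.58), the photoreceptor membrane protein LRIT1 (6.51 ± 0.44) and GNAT2 (6.36 ± 0.44). Of 23 pan-photoreceptor genes 18 were higher and 1 lower, 20 and 1 adjusted over the list alone (median 4.66, camera adjusted p = 1.34e-51). Lower in GFP-positive cells were SYT10 (-3.42 ± 0.94), the matrix protein SVEP1 (-3.02 ± 0.91), the glycine receptor GLRA2 (-3.02 ± 0.59), HOXA5 (-2.92 ± 0.66) and the collagen COL21A1 (-2.88 ± 0.74). Of 33 cell cycle genes 20 were lower and 0 higher, 30 and 0 adjusted over the list alone (median -1.38, camera adjusted p = 7.83e-18; adjusted p = 0.159 with an estimated correlation). edgeR called 1660 genes, 987 higher and 673 lower. That count was 954 without GFP-positive replicate 3, 839 without GFP-negative replicate 1, 589 without GFP-negative replicate 2 and 967 with the libraries of day 37 alone. The balance of directions moved too, with 744 higher and 210 lower without GFP-positive replicate 3, 540 and 299 without GFP-negative replicate 1, 491 and 98 without GFP-negative replicate 2, and 914 and 1110 by limma-voom. Among the lower genes the calls of SYT10 and SVEP1 were lost whichever library of day 37 was left out (highest adjusted p = 0.25 and 0.212, without GFP-negative replicate 1). COL21A1 was lost without GFP-negative replicate 1 (adjusted p = 0.227), GFP-positive replicate 1 or GFP-positive replicate 3, and GLRA2 (adjusted p = 0.0761) and HOXA5 (0.079) without GFP-negative replicate 2. The log2 value was then between 68.7% and 116% of that with all libraries.

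By day 47 CRX stood at 703 ± 66.4 against 42.5 ± 11.9 CPM (4.04 ± 0.30, adjusted p = 5.7e-07). LHX3 (6.49 ± 0.79), SSTR5 (6.11 ± 1.02), RAX2 (5.49 ± 0.67) and DBX1, a homeobox gene of early neural progenitors (5.48 ± 1.18), were higher in GFP-positive cells. HIST2H2AA4, a histone gene with a near-identical copy whose reads cannot be assigned with certainty, was at least 261-fold higher. The anion transporter SLC26A7 (-3.45 ± 0.72), the interferon-induced IFI44L (-3.04 ± 0.76), the neuropeptide precursor TAC1 (-2.84 ± 0.80), ANGPTL1 (-2.81 ± 0.64) and the cilium gene SPAG17 (-2.79 ± 0.51) were lower. Cone genes were higher in 14 of 17 cases, 15 adjusted over the list alone, with a median of 4.00, or 3.36 with genes at their bound (camera adjusted p = 4.48e-22). edgeR called 3579 genes, 1757 higher and 1822 lower, and 1867 without GFP-negative replicate 1. IFI44L lost its call without GFP-negative replicate 2 (adjusted p = 0.158). TAC1 lost it without either GFP-negative library, GFP-positive replicate 2 or GFP-positive replicate 3. With 1 library left out the log2 of TAC1 ran from -3.83 to -2.43. Over the 5 lost calls of named genes the value was between 61.6% and 106% of that with all libraries.

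Day 67 brought CRX to 939 ± 240 against 89.5 ± 23.3 CPM (3.38 ± 0.29, adjusted p = 2.37e-06). Higher in GFP-positive cells were MUSTN1 (6.63 ± 1.89), RAX2 (4.97 ± 0.63), SSTR5 (4.93 ± 0.93), LHX3 (4.84 ± 0.68) and the calcium channel CACNA1S (4.75 ± 0.82). In GFP-negative cells the epithelial gene BNC1 (-6.09 ± 1.81), the matrix protein ASPN (-5.83 ± 1.49), HOXA3 (-5.62 ± 0.81) and RSPO3 (-5.38 ± 1.15) were higher. Müller glia genes were lower in GFP-positive cells in 15 of 19 cases and higher in 1 by both adjustments (median -2.32, camera adjusted p = 1.63e-08; adjusted p = 0.0571 with an estimated correlation). edgeR called 5218 genes, 2428 higher and 2790 lower, with 3102 and 3255 without GFP-negative replicates 1 and 2. Leaving out GFP-negative replicate 2 ended the calls of ASPN (log2 -2.06, adjusted p = 0.357), BNC1 (-4.13, adjusted p = 0.151), MUSTN1 (5.65, adjusted p = 0.116) and RSPO3 (-2.76, adjusted p = 0.0954). MUSTN1 was also lost without GFP-negative replicate 1 (log2 10.91), and BNC1 without GFP-positive replicate 1 or 2.

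At day 90 CRX was at 1237 ± 167 against 259 ± 67.5 CPM (2.24 ± 0.27, adjusted p = 3.73e-05). SSTR5 (5.09 ± 0.94), the opioid receptor OPRD1 (4.64 ± 1.08), the small GTPase RRAD (4.53 ± 0.84) and LHX3 (4.49 ± 0.66) were higher in GFP-positive cells, as was SYS1-DBNDD2 (6.58 ± 1.83), a readthrough of neighbouring genes that shares their reads. In GFP-negative cells AREGB, a copy of the growth factor gene AREG (-9.45 ± 2.28), C19orf33 (-5.20 ± 1.67), the epithelial splicing factor ESRP1 (-5.09 ± 1.63), EPSTI1 (-4.66 ± 1.08) and the neuropeptide neurotensin, NTS (-4.65 ± 1.02), were higher. The calls of these 5 genes depended on 1 library, while NTS kept most of its log2 value without it. Without GFP-negative replicate 2 none was called, with an adjusted p of 0.729 for AREGB (log2 -1.31), 0.674 for C19orf33 (-1.27), 0.537 for ESRP1 (-1.62), 0.506 for EPSTI1 and 0.0606 for NTS (-2.95). In that library the median of 35 intestinal epithelium markers was 33.6 CPM, against 0.203 in the other GFP-negative library of the day. C19orf33 was also lost without any 1 of the GFP-positive libraries, ESRP1 without GFP-positive replicate 1 or 3, and SYS1-DBNDD2 without GFP-negative replicate 1. Over the 11 lost calls of named genes at this day the log2 value was between 13.8% and 109% of that with all libraries (median 85.7%). Amacrine and horizontal cell genes were lower in GFP-positive cells in 12 of 22 cases and higher in 2, 13 and 3 adjusted over the list alone (median -2.01, camera adjusted p = 1.47e-05). Ganglion cell genes were lower in 13 of 17 cases and higher in 1 by both adjustments (median -2.02, camera adjusted p = 0.000239; adjusted p = 0.305 with an estimated correlation). edgeR called 5765 genes, 2607 higher and 3158 lower, with 3838 and 3728 without GFP-negative replicates 1 and 2. Over the 4 days 692 genes were called higher and 510 lower at every day, and 32 were called in opposite directions on different days.

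**Figure D3:**
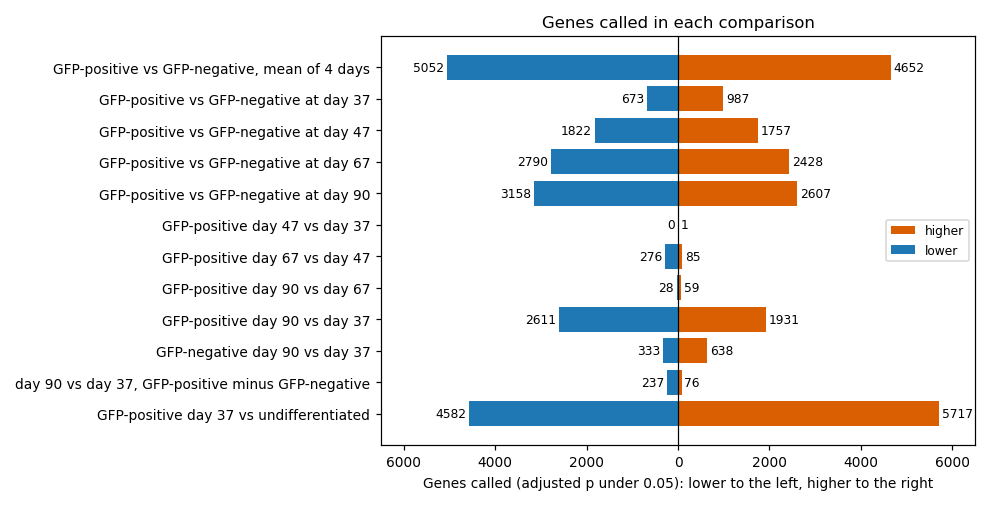
Number of genes called by edgeR at an adjusted p under 0.05 in each of the 12 comparisons, with bars from 0 for genes called higher and genes called lower. The step from day 37 to day 47 holds 1 gene and the comparison with undifferentiated cells 10299.

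Changes over time within GFP-positive cells asked how these cells matured. Between days 37 and 90, 20 of 23 pan-photoreceptor genes and 17 of 24 synapse genes rose, as did the rod regulators NRL and NR2E3. Cell cycle (28 of 33), neurogenic precursor (12 of 19) and ganglion cell genes (10 of 17) fell, as did members of the pigment epithelium (8 of 20), forebrain (6 of 14) and lens, mesenchyme and neural crest lists (6 of 17). None of these 6 falling lists passed camera with an estimated correlation (adjusted p = 0.204, 0.061, 0.145, 0.325, 0.2 and 0.257). CRX rose from 404 ± 101 to 1237 ± 167 CPM (log2 1.63 ± 0.23, adjusted p = 8.73e-05). SAMD7 (7.39 ± 1.15), OPRD1 (6.52 ± 1.02), the interphotoreceptor matrix proteoglycan IMPG1 (6.32 ± 0.57), the disc protein PRPH2 (6.14 ± 0.78) and NR2E3 (ENSG00000031544, chromosome 15, 72102894 to 72110600; 5.96 ± 0.93) rose the most. Genes high at day 37 and nearly gone by day 90 were the serpin SERPINI2 (-8.80 ± 1.14), the transcription factor SIM1 (-8.21 ± 0.74), DBX1 (-8.18 ± 1.17), NTS (-7.55 ± 1.09) and SLC35D3 (-6.43 ± 1.78). SERPINI2 went from 68.6 ± 14.2 to 0.136 ± 0.11 CPM.

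Rod genes rose in 8 of 16 cases, 10 adjusted over the list alone, and none fell (median 2.07, camera adjusted p = 1.1e-05; adjusted p = 0.0724 with an estimated correlation). NRL (ENSG00000129535, chromosome 14, 24549316 to 24584223) went from 7.11 ± 3.84 to 245.0 ± 149 CPM (5.11 ± 0.70, adjusted p = 8.31e-05), NR2E3 from 0.731 ± 0.407 to 44.3 ± 28.1 and the rod transducin GNAT1 from 1.40 ± 0.746 to 35.4 ± 30.0. Cone genes rose in 12 of 17 cases and fell in 1, 13 and 2 adjusted over the list alone (median 2.65, camera adjusted p = 7.06e-12; adjusted p = 0.061 with an estimated correlation). GUCA1C (5.89 ± 0.95), KCNV2 (4.26 ± 0.47), PDE6H (4.03 ± 0.40), RXRG (3.06 ± 0.32) and cone arrestin, ARR3 (2.65 ± 0.39), rose. THRB was at 970.5 ± 223 and 687 ± 148 CPM (-0.48 ± 0.20, adjusted p = 0.092). The blue cone opsin OPN1SW was at 0.494 ± 0.225 and 0.669 ± 0.334 CPM (adjusted p = 0.615). Pan-photoreceptor genes rose in 20 of 23 cases and fell in 1, 21 and 1 adjusted over the list alone (median 2.08, camera adjusted p = 1.88e-22), with RP1 of the outer segment axoneme at 5.93 ± 0.60 and RCVRN at 3.54 ± 0.36. Synapse genes rose in 17 of 24 cases and fell in 2, 18 and 3 adjusted over the list alone (median 1.27, camera adjusted p = 7.06e-12). Against the group, RIMS1 of the active zone fell by 4.15 ± 0.45. Of 42 ciliary genes 18 rose and 1 fell, 19 and 1 adjusted over the list alone (median 0.349, camera adjusted p = 1.92e-06; adjusted p = 0.227 with an estimated correlation), such as the kinase MAK (2.83 ± 0.36) and CC2D2A (2.23 ± 0.21).

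Cell cycle genes fell in 28 of 33 cases, 29 adjusted over the list alone (median -1.70, camera adjusted p = 1.82e-13; adjusted p = 0.204 with an estimated correlation), with the mitotic genes KIF20A at -2.78 ± 0.36 and AURKB at -2.71 ± 0.49. MKI67 went from 69.2 ± 42.9 to 16.0 ± 4.66 CPM (-2.11 ± 0.40). Neurogenic precursor genes fell in 12 of 19 cases and rose in 1, 13 and 2 adjusted over the list alone (median -1.15, camera adjusted p = 5.11e-06; adjusted p = 0.061 with an estimated correlation), among them ONECUT2 (-3.15 ± 0.29) and OLIG2 (-3.10 ± 0.37). Ganglion cell genes fell in 10 of 17 cases and rose in 1, 12 and 1 adjusted over the list alone (median -1.81, camera adjusted p = 1.21e-06; adjusted p = 0.145 with an estimated correlation), such as the synuclein SNCG (-5.49 ± 0.81), the neurofilament NEFM (-4.12 ± 0.52) and POU4F2 (-3.86 ± 0.67). Progenitor genes fell in 13 of 22 cases and rose in 1 by both adjustments (median -0.943, camera adjusted p = 0.00108; adjusted p = 0.267 with an estimated correlation), led by FGF19 (-4.77 ± 0.57) and the WNT inhibitor SFRP2 (-3.17 ± 0.46). Pigment epithelium genes fell in 8 of 20 cases and rose in 2, 9 and 3 adjusted over the list alone (median -1.58, camera adjusted p = 0.00788; adjusted p = 0.325 with an estimated correlation), among them the melanosome genes PMEL (-4.48 ± 1.23) and TYRP1 (-4.26 ± 1.46). Forebrain genes fell in 6 of 14 cases (median -2.04, camera adjusted p = 0.00237; adjusted p = 0.2 with an estimated correlation) and lens, mesenchyme and neural crest genes in 6 of 17 (median -1.68, camera adjusted p = 0.00222; adjusted p = 0.257 with an estimated correlation). Retinoic acid response genes fell in 8 of 17 cases and rose in 1 (median -1.31, camera adjusted p = 0.00222; adjusted p = 0.204 with an estimated correlation), and counts adjusted over the list alone were equal for these 3 lists. edgeR called 4542 genes, 1931 higher and 2611 lower. TYRP1 was lost without GFP-positive replicate 1 or 3 of day 37 or replicate 1 or 2 of day 90 (highest adjusted p = 0.13). PMEL was lost without replicate 3 of day 37 or replicate 1 or 2 of day 90 (highest 0.0565, without replicate 2 of day 90), and SLC35D3 without replicate 1 or 2 of day 90 (highest 0.0551, without replicate 1 of day 90). With 1 library left out the log2 value ran from -6.21 to -3.60 for TYRP1, from -6.33 to -3.47 for PMEL and from -11.65 to -5.45 for SLC35D3.

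**Figure D4:**
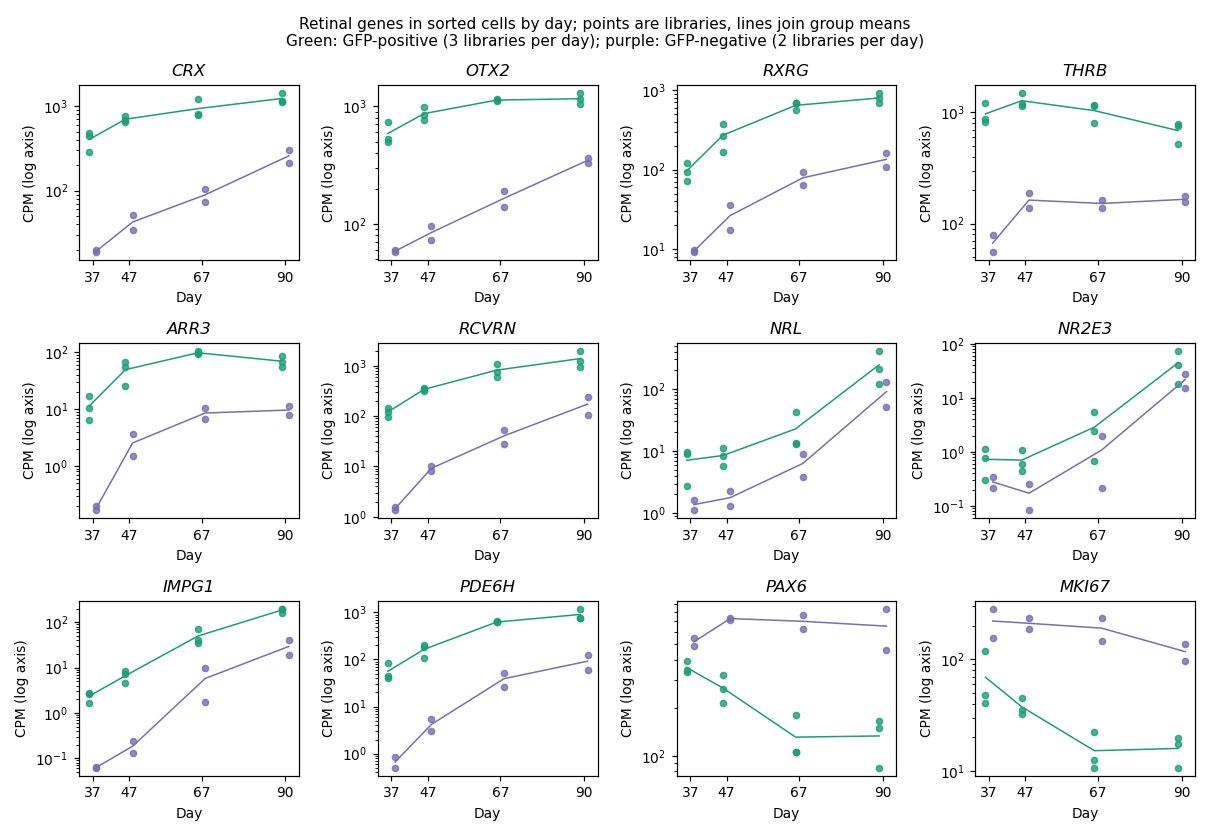
CPM (log axis) against day of differentiation for 12 genes in GFP-positive (3 libraries a day) and GFP-negative cells (2 libraries a day); points are libraries and lines join the means of a fraction. CRX rises from 404 to 1237 CPM in GFP-positive cells and from 19.2 to 259 CPM in GFP-negative cells.

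The steps between successive days were smaller. From day 37 to day 47 the only gene called by edgeR was TBCC (ENSG00000124659, chromosome 6, 42712219 to 42714558), a tubulin folding cofactor, which rose from 58.5 ± 2.83 to 111 ± 16.9 CPM (0.93 ± 0.12, adjusted p = 0.012). CRX (0.81 ± 0.22, adjusted p = 0.145), RXRG (1.51 ± 0.30, adjusted p = 0.0684), RCVRN (1.51 ± 0.33, adjusted p = 0.0895) and ARR3 (2.15 ± 0.39, adjusted p = 0.0587) did not pass the test over all genes. With the replicate number as a block edgeR called RXRG (adjusted p = 0.0311), RCVRN (0.0318) and ARR3 (0.0202), and the DESeq2 Wald test called these 3 (0.000351, 0.00152 and 4.68e-05) and CRX (0.0292). Without replicate 3 of day 47 edgeR called RXRG (0.0155), RCVRN (0.0497) and ARR3 (0.0141), and ARR3 also without replicate 1 of day 37 (0.0451). As groups, pan-photoreceptor genes (median 0.942, camera adjusted p = 8.46e-18) and cone genes (median 1.11, camera adjusted p = 8.27e-13) were higher at day 47, with 15 of 23 and 10 of 17 higher adjusted over the list alone and 0 over all genes; 2028 genes had an unadjusted p under 0.05. The DESeq2 Wald test called 451, and edgeR with the replicate number as a block 284. The single call was lost without GFP-positive replicate 2 of day 37 (adjusted p = 0.106), replicate 3 of day 37 or replicate 2 of day 47, where edgeR called 0 genes with 1619, 1476 and 1246 at an unadjusted p under 0.05. It called 45 genes without replicate 1 of day 37 and 232 without replicate 3 of day 47.

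From day 47 to day 67 edgeR called few members of the lists, 4 of 17 cone genes higher and 3 of 22 progenitor genes lower among them. CRX was at 703 ± 66.4 and 939 ± 240 CPM (0.44 ± 0.22, adjusted p = 0.377). IMPG1 (2.94 ± 0.49, adjusted p = 0.0121), RP1 (2.57 ± 0.51), the homeobox gene IRX6 (2.51 ± 0.42), C4orf6 (2.32 ± 0.43) and the collagen COL4A3 (2.21 ± 0.53) rose the most among genes at 5 CPM or more. DBX1 (-4.92 ± 0.96), SERPINI2 (-4.45 ± 0.89), the protease ADAMTS9 (-3.63 ± 0.87), the gap junction protein GJA1 (-3.51 ± 0.68) and HAS2, which makes hyaluronan (-3.45 ± 0.62), fell the most. Cone genes rose in 4 of 17 cases, 11 adjusted over the list alone (median 1.01, camera adjusted p = 7.83e-11; adjusted p = 0.0891 with an estimated correlation). These 4 were GUCA1C (3.47 ± 0.83), PDE6H (1.95 ± 0.36), GNGT2 (1.51 ± 0.38) and RXRG (1.27 ± 0.30). In the rod list SAMD7 alone rose (5.00 ± 1.08; median of the list 0.549, camera adjusted p = 0.00414; adjusted p = 0.164 with an estimated correlation), again 1 adjusted over the list alone. Progenitor genes fell in 3 of 22 cases, 11 adjusted over the list alone (median -0.783, camera adjusted p = 3.62e-09; adjusted p = 0.127 with an estimated correlation). They were FGF19 (-2.81 ± 0.52), SFRP2 (-1.98 ± 0.44) and HES1 (-1.33 ± 0.31). NEFM of the ganglion cell list fell by 2.39 ± 0.48. edgeR called 361 genes, 85 higher and 276 lower, and 912 with the replicate number as a block. Calls at this step were lost when libraries were left out, while the changes kept most of their size. The count was 147, 627 and 2 without GFP-positive replicates 1, 2 and 3 of day 47 and 13, 0 and 634 without replicates 1, 2 and 3 of day 67, and 0 with the libraries of both days alone. Of the 19 called genes named here, none stayed called without replicate 3 of day 47 or replicate 2 of day 67. IMPG1 alone stayed called without replicate 1 of day 67, 10 stayed without replicate 1 of day 47 and 17 without replicate 2 of day 47 or replicate 3 of day 67. Over the 69 lost calls the log2 value was between 62.5% and 127% of that with all libraries (median 93.3%), and IMPG1 stayed between 2.56 and 3.13 in all 6 fits. Where edgeR called 0 genes, 1755 had an unadjusted p under 0.05 without replicate 2 of day 67 and 1943 with the libraries of both days alone, against 2567 with all libraries. DESeq2 called 997 (247 higher and 750 lower) and limma-voom 219 (101 and 118) with all libraries, and edgeR with the block 287 higher and 625 lower.

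From day 67 to day 90 NRL and NR2E3 were the called members of the rod list, and both rose. No cone gene was called, but the difference between the rod and cone lists was not tested. CRX was at 939 ± 240 and 1237 ± 167 CPM (0.39 ± 0.22, adjusted p = 0.547). GRAMD1C (4.67 ± 0.91), the neurotransmitter transporter SLC6A17 (4.52 ± 0.65, adjusted p = 0.0079), the magnesium transporter NIPAL1 (4.44 ± 0.84), NR2E3 (3.92 ± 0.83) and MXRA5 (3.80 ± 0.78) rose the most. Those that fell the most were RIMS1 (-2.33 ± 0.41), the amino acid transporter SLC38A4 (-2.14 ± 0.35), the kinase PAK6 (-2.02 ± 0.43), the sarcomere gene NEB (-2.00 ± 0.33) and the potassium channel KCNQ5 (-1.99 ± 0.42). Of 16 rod genes 2 rose, NRL (3.41 ± 0.65) and NR2E3, and 7 adjusted over the list alone (median 0.759, camera adjusted p = 5.48e-08; adjusted p = 0.072 with an estimated correlation). Of 17 cone genes 0 were called by either adjustment (median 0.512, camera adjusted p = 0.457), for example ARR3 at 98.4 ± 6.90 and 69.9 ± 15.6 CPM (-0.52 ± 0.37, adjusted p = 0.672) and RXRG (0.29 ± 0.29, adjusted p = 0.811). MEF2C, a transcription factor of rods, rose by 1.53 ± 0.27, the disc protein ROM1 by 2.17 ± 0.41 and RLBP1, the retinal-binding protein of Müller glia, by 2.52 ± 0.51. Neurogenic precursor genes fell in 1 of 19 cases, 7 adjusted over the list alone (median -0.486, camera adjusted p = 2.66e-09; adjusted p = 0.0555 with an estimated correlation), with OLIG2 at -1.79 ± 0.35. STMN2 of the ganglion cell list fell by 1.35 ± 0.28. edgeR called 87 genes, 59 higher and 28 lower, and 264 with the replicate number as a block. Without GFP-positive replicate 2 of day 67 the balance turned to 19 higher and 26 lower, and each other fit with 1 library left out called more genes higher than lower. The count was 8, 45 and 5 without GFP-positive replicates 1, 2 and 3 of day 67, 18 and 10 without replicates 1 and 2 of day 90, and 0 with the libraries of both days alone (1828 at an unadjusted p under 0.05, against 1948 with all libraries, where DESeq2 called 457). Of the 16 called genes named here, 0 stayed called without replicate 1 of day 67. Without replicate 2 or 3 of day 67, 10 and 1 stayed, and without replicates 1, 2 and 3 of day 90, 3, 1 and 12. NRL was lost in 4 of the 6 fits with 1 library left out and NR2E3 in 5 (highest adjusted p = 0.176 and 0.281, both without replicate 2 of day 90). Their log2 values ran from 2.81 to 4.21 and from 3.32 to 4.85 over these fits, and over the 69 lost calls the value was between 66.5% and 124% of that with all libraries (median 99%).

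The change in GFP-negative cells between days 37 and 90 asked whether cells without GFP also altered with age. Photoreceptor genes rose in them, and 4 of 17 retinoic acid response genes fell. CRX rose from 19.2 ± 0.898 to 259 ± 67.5 CPM (3.73 ± 0.30, adjusted p = 3.78e-06). Pan-photoreceptor genes rose in 18 of 23 cases, 19 adjusted over the list alone, and none fell (median 4.14, camera adjusted p = 9.8e-62), such as RP1 (9.03 ± 0.92), IMPG1 (8.83 ± 0.90), PRPH2 (8.23 ± 1.18) and RCVRN (6.89 ± 0.52). Photoreceptor transcription factors rose in 13 of 16 cases by both adjustments (median 2.35, camera adjusted p = 4.59e-32), with NR2E3 (6.24 ± 1.18), NRL (6.03 ± 0.92) and RXRG (3.81 ± 0.41). Cone genes rose in 10 of 17 cases, with 11 higher and 1 lower adjusted over the list alone (median 3.81, or 3.79 with genes at their bound, camera adjusted p = 1.33e-28), among them KCNV2 (7.63 ± 0.77) and PDE6H (7.09 ± 0.59). Rod genes rose in 7 of 16 cases by both adjustments (median 1.94, camera adjusted p = 6.98e-09). Of 17 retinoic acid response genes 4 fell, 5 adjusted over the list alone (median -0.886, camera adjusted p = 5.01e-05; adjusted p = 0.106 with an estimated correlation), led by CYP26A1 (-3.39 ± 0.81) and CYP26B1 (-3.14 ± 0.61), which degrade retinoic acid. Cell cycle genes fell in 7 of 33 cases, 26 adjusted over the list alone (median -1.10, camera adjusted p = 2.15e-13; adjusted p = 0.226 with an estimated correlation), with CDC20 at -1.74 ± 0.45 and KIF20A at -1.64 ± 0.42.

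The genes with the highest change were the hormone precursor GCG, at least 724-fold higher from no counts, TM4SF20, at least 245-fold higher from no counts, MYO7B, the membrane protein TSPAN8 (10.78 ± 2.93) and the intestinal stem cell gene OLFM4 (ENSG00000102837, chromosome 13, 53602894 to 53626192; 10.33 ± 2.43). MYO7B, an intestinal brush border myosin, went from 0.0135 ± 0.0167 to 28.6 ± 40.2 CPM. All 5 rested on GFP-negative replicate 2 of day 90, where OLFM4 was at 475 CPM against 2.25 in replicate 1. Without that library their adjusted p lay between 0.389 and 0.545. A list of 35 other intestinal epithelium markers, written after these genes had been seen, had a median of 33.6 CPM in that library, 0.203 in replicate 1, 1.49 in GFP-positive replicate 2 and 0.709 in GFP-positive replicate 3 of day 90. The lowest changes were those of SYS1-DBNDD2 (-6.80 ± 1.88), the serotonin receptor HTR2C (-5.54 ± 1.48), the NODAL inhibitor LEFTY2 (-4.44 ± 1.08), CLEC19A (-4.17 ± 0.84) and the growth factor FIGF (-3.98 ± 0.74).

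edgeR called 971 genes, 638 higher and 333 lower, and 321, 423 and 514 without GFP-negative replicate 1 of day 37, replicate 2 of day 37 and replicate 2 of day 90. The balance of directions moved too, with 250 higher and 71 lower, 336 and 87, and 441 and 73 in these 3 fits, 714 and 135 without replicate 1 of day 90, and 581 and 518 by limma-voom. With the replicate number as a block it called 1710, and 1488 with the numbers of the GFP-negative libraries of day 90 crossed. With the libraries of both groups alone it called 347, and DESeq2 called 1798 with all. The 5 intestinal genes were also lost without either library of day 37, as was LEFTY2, which was lost too without replicate 2 of day 90 (adjusted p = 0.167). HTR2C, CDC20 and KIF20A were lost whichever of the 4 libraries was left out. Their log2 values then ran from -7.275 to -4.76, from -1.89 to -1.495 and from -1.74 to -1.38. CYP26A1 was lost without replicate 2 of day 37 (adjusted p = 0.184) or either library of day 90, and SYS1-DBNDD2 without replicate 1 of day 37 (adjusted p = 0.506) or either library of day 90. NR2E3 was lost without either library of day 37, and CLEC19A and FIGF without replicate 2 of day 90. Over the 4 fits their log2 values ran from 5.77 to 6.72, from -4.44 to -3.67 and from -5.07 to -3.31. Over the 40 calls of named genes lost in these fits the log2 value was between 33% and 163% of that with all libraries (median 94.9%). The photoreceptor genes CRX, RXRG, NRL, KCNV2, PDE6H, RP1, IMPG1, PRPH2 and RCVRN were called in all 4 of these fits.

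**Figure D5:**
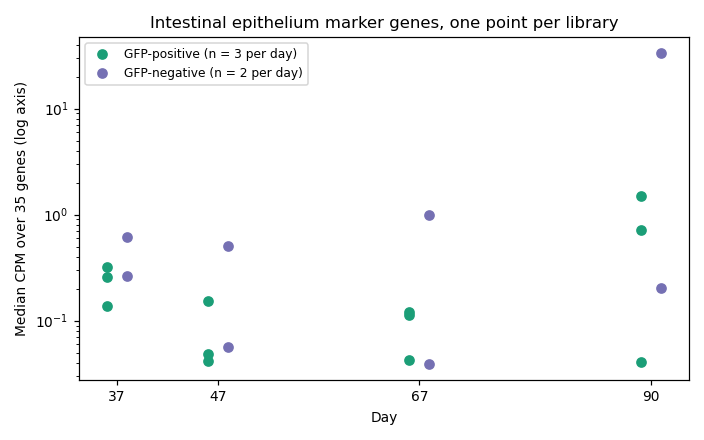
Median CPM of 35 intestinal epithelium markers (log axis) in each of the 20 sorted libraries, by group; each point is a library. GFP-negative replicate 2 of day 90 is at 33.6 CPM and the other 19 libraries at 1.49 CPM or less.

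The interaction asked whether the fractions changed differently between days 37 and 90. CRX rose in both, by 1.63 ± 0.23 in GFP-positive and 3.73 ± 0.30 in GFP-negative cells, and the difference was -2.11 ± 0.35 (adjusted p = 0.00839). On the log2 scale, which compares ratios and not CPM, a negative difference means a smaller rise or a larger fall in GFP-positive cells. Photoreceptor transcription factors had a lower change in GFP-positive cells in 7 of 16 cases, with 9 lower and 1 higher adjusted over the list alone (median -1.45, camera adjusted p = 6.43e-11), among them the nuclear receptor ESRRB (-3.31 ± 0.71), PRDM1, which holds photoreceptor fate (-2.84 ± 0.35), and NEUROD4 (-2.83 ± 0.42). Neurogenic precursor genes did so in 7 of 19 cases, with 13 lower and 1 higher adjusted over the list alone (median -1.42, camera adjusted p = 1.72e-12), such as ONECUT2 (-3.30 ± 0.43), ONECUT1 (-2.99 ± 0.60) and OLIG2 (-2.97 ± 0.55). Amacrine and horizontal cell genes did so in 6 of 22 cases, with 13 lower and 2 higher adjusted over the list alone (median -1.73, camera adjusted p = 2.83e-09). Of 23 pan-photoreceptor genes 10 had a lower change, with 12 lower and 2 higher adjusted over the list alone (median -2.16, camera adjusted p = 7.12e-12; adjusted p = 0.0647 with an estimated correlation), among them PDC (-4.26 ± 0.53), IMPG2 of the interphotoreceptor matrix (-3.52 ± 0.56) and RCVRN (-3.36 ± 0.55). PDE6C (-3.39 ± 0.67) and GNAT2 (-3.32 ± 0.50) of the cone list had lower changes too, as had EBF1 (-2.92 ± 0.71) and STMN2 (-2.92 ± 0.44), which are active in young neurons. The largest differences were those of NTS (-8.03 ± 1.48), SPINK4 (-7.25 ± 1.29), SERPINI2 (-6.80 ± 1.55), ONECUT3 (-6.11 ± 0.78) and SIM1 (-6.11 ± 1.05) on the lower side. PRR16 (2.61 ± 0.61), the growth factor GDF10 (2.58 ± 0.61), the phosphatase subunit PPP2R2B (2.57 ± 0.58), the protocadherin PCDHAC2 (2.48 ± 0.54) and PCOLCE2 (2.42 ± 0.49) were on the higher side. edgeR called 313 genes, 76 higher and 237 lower, and 682 with the replicate number as a block, with 30 and 90 without GFP-negative replicates 1 and 2 of day 37 and 185 and 173 without GFP-positive replicates 1 and 3 of day 90. Without GFP-negative replicate 1 of day 37 the call of CRX was lost (-2.09, adjusted p = 0.0783). Of the 24 genes named here, 20 and 11 lost their call without GFP-negative replicates 1 and 2 of day 37, 10 and 2 without GFP-negative replicates 1 and 2 of day 90, 3, 7 and 5 without GFP-positive replicates 1, 2 and 3 of day 37 and 5, 5 and 7 without GFP-positive replicates 1, 2 and 3 of day 90. Where a call was lost the log2 value was between 58.3% and 120% of that with all libraries (median 97.4%).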

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

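The tests of carried-over cells at 1 share, of scaling, of the early genes higher in GFP-positive cells at day 37 and of the share that limits carry-over at day 37 were chosen only after the results had been seen. Between days 37 and 90 the fractions changed differently for 313 genes by the interaction test, and the genes below drew attention because that test called them. These differences compare ratios and not CPM. CRX in GFP-negative cells reached 259 CPM at day 90, below the 404 CPM of GFP-positive cells at day 37. CRX rose in both fractions, and its rise on the log2 scale was smaller in GFP-positive cells (log2 difference -2.11). Photoreceptor genes differed the same way, namely PDC (-4.26), IMPG2 (-3.52), PDE6C (-3.39), RCVRN (-3.36), GNAT2 (-3.32), ESRRB (-3.31), PRDM1 (-2.84) and NEUROD4 (-2.83). Members of the neurogenic precursor list were ONECUT2 (-3.30), ONECUT1 (-2.99) and OLIG2 (-2.97), and of the ganglion cell list EBF1 (-2.92) and STMN2 (-2.92). In no list, NTS (-8.03), SPINK4 (-7.25), SERPINI2 (-6.80), ONECUT3 (-6.11) and SIM1 (-6.11) lay lowest, where SPINK4 had no counts in GFP-negative cells of day 37 and its value depends on the prior count. PRR16 (2.61), GDF10 (2.58), PPP2R2B (2.57), PCDHAC2 (2.48) and PCOLCE2 (2.42) had a higher change in GFP-positive cells. Without GFP-negative replicate 1 of day 37 the test called 30 genes and not CRX (adjusted p = 0.0783), and the counts without the other libraries ran up to 354.

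The rise of photoreceptor genes in GFP-negative cells went with many of these differences. If GFP-positive cells had been carried into the GFP-negative sort of day 90 at 1 common share, rod and cone genes would show the same share of their level in GFP-positive cells of the same number. The median share was 20.3% for 6 rod genes and 11.6% for 9 cone genes in replicate 1, and 28.2% and 16.7% in replicate 2. The ratio was at least 1.68 with a permutation p over genes of 0.003 in each library. Genes are not independent replicates, and this p does not measure the spread between libraries. Rod genes such as NRL varied widely between the GFP-positive libraries of day 90. The ratio goes against 1 common share as the whole cause only if same-numbered libraries share a culture, which the labels do not give. Scaling of the libraries is excluded. A factor per library moves all genes alike, whereas the median of 23 pan-photoreceptor genes lay 4.15 above that of all genes on the log2 scale (10000 random lists gave -0.649 to 0.713) and the cell cycle list at -1.09. Cells that carry photoreceptor RNA with dim GFP, or carried-over cells like or unlike the GFP-positive pool, may explain the rise, and the tables do not tell these apart.

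Genes high in GFP-positive cells of day 37 and nearly absent by day 90 formed another pattern, with 28 genes that were below 5% of their day 37 level. Of these 8 (28.6%) were called higher in GFP-positive than in GFP-negative cells at day 37, namely DBX1, SERPINI2, SIM1, NEB, SHOX2, ONECUT3, NTS and BHMT. Cells carried into the GFP-positive sort of day 37 with the levels of the GFP-negative pool cannot bring a gene above its level in that pool. That form of carry-over is argued against for these 8, which were chosen by this difference. Carried cells that differ from the pool are not excluded. For the 8 of the 28 with a log2 value below 0 at day 37 the median was -1.19 (interquartile range 1.31). Cells carried from the GFP-negative pool at 1 share would bring its other genes at that share as well, so genes that stay low in GFP-positive cells limit it. The 20 genes at 5 CPM or more in GFP-negative cells of day 37 with the lowest mean log2 value at days 47, 67 and 90, among those called lower at each of these days, had a median of -1.80 at day 37. The 8 genes lay 0.60 above it, with a Wilcoxon p over genes of 0.0247 (0.0117 to 0.0301 with 5, 10 or 40 limiting genes), and 0.11, 0.32 and 1.02 above it in GFP-positive replicates 1, 2 and 3. The 8 genes were chosen by their level in GFP-positive cells of day 37, which can by itself raise their log2 value. The limiting genes were not chosen by that level, so the gap does not decide on carry-over of the pool at 1 share. Such carry-over, carried cells that differ from the pool and expression in GFP-positive cells cannot be told apart for this part. The interquartile range is too wide to show 1 share. A biological change of GFP-positive cells with age stays open for both parts.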

How the results depend on the processing

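The other treatments of the undifferentiated columns and the crossed block were tested only after the data had been seen. Counts are set against those of edgeR with all libraries, and a count is said to keep within 1.5 times of it or not. All 12 counts kept within that range with DESeq2 size factors, no filter and the filter of 1 CPM, 10 with limma-voom, 8 with a minimum change of 2-fold, 7 with the DESeq2 Wald test, 7 with the replicate block and 6 with only the libraries of the groups compared, which does not apply to the mean of 4 days.

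The DESeq2 Wald test called 451 genes for GFP-positive cells from day 37 to 47, 997 from day 47 to 67, 457 from day 67 to 90, 1798 for GFP-negative cells and 951 for the interaction; limma-voom called 5 from day 37 to 47 and 219 from day 47 to 67. A minimum change of 2-fold, which is stricter by construction, left 4131 genes for the mean of 4 days, 2343 at day 47, 0 from day 37 to 47 (2028 at an unadjusted p under 0.05 with no minimum change) and 2784 from day 37 to 90 in GFP-positive cells. With only the libraries compared, which leaves fewer samples to estimate the spread, edgeR called 967 genes between fractions at day 37, 347 in GFP-negative cells and 0 in each successive step, where 1423, 1943 and 1828 genes had an unadjusted p under 0.05. The replicate block gave 284, 912 and 264 genes for the 3 successive steps, 1710 for GFP-negative cells and 682 for the interaction. Crossing the numbers of the GFP-negative libraries of day 90, tried for the GFP-negative change alone, gave 1488. All other libraries kept their numbers, so this does not show whether the gain rests on the numbers as given. Apart from the settings whose construction is named, the cause was not tested. An estimated correlation between genes took the called list tests from 187 to 46, and fry called 161.

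Leaving out 1 library at a time gave 8854 to 9925 genes for the mean of 4 days, 589 to 1590 at day 37, 1867 to 3858 at day 47, 3102 to 5284 at day 67 and 3728 to 4979 at day 90. The successive steps gave 0 to 232, 0 to 634 and 5 to 94, GFP-positive cells from day 37 to 90 gave 3466 to 4395, GFP-negative cells 321 to 849, the interaction 30 to 354 and the comparison with undifferentiated cells 7812 to 10710. The lowest of these came without GFP-negative replicate 2 at days 37 and 90, without GFP-negative replicate 1 at days 47 and 67, and without GFP-negative replicate 1 of day 37 for the GFP-negative change and the interaction. Where 1 library was left in a group, that lone sample was assumed to vary like the other groups. Undifferentiated columns as deposited gave 7344 genes, the first and second columns alone 10303 and the third column, realigned, as its own library 11850.

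The 257 named gene results had 4293 values under alternatives, of which 3868 stayed on their side of the threshold, 414 lost the call, 11 gained it and 0 changed direction. Of the losses 308 came from leaving out a library, 52 from only the libraries compared and 37 from limma-voom. An alternative with eXpress effective counts was not run, because only estimated counts were deposited. Depth was even, from 40.6 M to 52.6 M estimated counts (M, 1e6). No alternative with a lower depth was run, so the effect of depth on the counts above was not tested.

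Random splits were set beside the counts of genes. For the mean of 4 days 1 of 60 splits, the real one, reached 9704 genes and the highest other gave 2048. This argues against chance, but 1 in 60 is the lowest share these splits can give. They also treat the libraries of a day as exchangeable. The 10 splits of 6 libraries are too few for a share under 0.05. The real split gave 1 gene from day 37 to 47 (highest other 6, so 2 splits reached the real count), 361 from day 47 to 67 (highest other 0), 87 from day 67 to 90 (highest other 0) and 4542 from day 37 to 90 (highest other 0).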

Other observations

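Both tests of this part used a list of intestinal markers, and the test for an outside sample was chosen only after the result had been seen. GFP-negative replicate 2 of day 90 held RNA of genes typical of intestinal epithelium. OLFM4 of intestinal stem cells was at 475 CPM against 2.25 in replicate 1, TSPAN8 at 328 against 1.37 and the mucin MUC13 at 252 against 0.242. These genes were chosen after their values were seen. A list of 35 markers was higher in that library by a median log2 of 6.01, with 31 of 35 at least 4-fold higher, where 95% of 10000 random lists of genes of like level lay from -0.2 to 0.234. Of the 35 markers 5 reached 1 CPM in the median of the other 19 sorted libraries, and 0 are in the fixed lists.

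Cells of an intestinal epithelium type in the culture are a candidate source, and the sort for GFP-negative cells would not remove them, while the sort for GFP-positive cells would. RNA from an outside sample that entered this library alone is argued against. The markers were also higher in GFP-positive replicate 2 than in replicate 1 of day 90 (median log2 3.3, 26 of 35 at least 4-fold). Of the random lists 95% lay from -0.0774 to 0.208. These lists were matched to levels in the GFP-negative libraries of day 90. They therefore do not show the spread of genes as low as the markers in GFP-positive cells. The markers were not limited to replicate 2 or to day 90. Their median was 0.709 CPM in GFP-positive replicate 3 of day 90 against 0.0408 in replicate 1, and 0.982 in GFP-negative replicate 2 of day 67 against 0.0389 in replicate 1, where FABP1 reached 11.7 and CDH17 23.9 CPM (both chosen after their values were seen). RNA spread from GFP-negative replicate 2 of day 90 at 1 share would keep the proportions of its genes. OLFM4 and CDH17 were at 475 and 410 CPM there and at 17.1 and 24.7 in GFP-positive replicate 2. GFP-negative replicate 2 of day 67 had 0.846 and 23.9, and replicate 1 of day 37 had 0.0861 and 10.7. These values, chosen after they were seen, argue against such spread as the source of CDH17 at days 67 and 37. Beyond that, intestinal cells in several cultures and RNA spread in shared handling may each explain the markers. The tables do not tell these apart. Whether replicate numbers mark cultures is not given, so no biological explanation was tested further.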
